A study of Pseudomonas [fluorescens] SBW25 with 8 samples.

How the data were processed

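Total RNA of 8 separate cultures of the soil and plant bacterium Pseudomonas fluorescens SBW25 was measured on single-colour NimbleGen expression arrays, 4 arrays for the wild type and 4 for a mutant with a plasposon (a transposon that carries a plasmid origin) inserted in gacS. Per the labels' protocols, cells came from PSA plates (48 h of growth, 25 °C), were washed 3 times, set to an optical density at 600 nm of 1.0 and spotted as 7 droplets of 5 μl on diluted PDA agar. RNA was labelled with Cy3 by the array maker, per the labels. Each label names the genotype and says that every replicate came from its own culture, so the spread between arrays includes biological variation.

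The authors deposited 1 scanner file per array. It holds the intensity of every spot on a linear scale, extracted from the image with NimbleScan 2.4.31, per the file headers. The mismatch column held only 0 and was not used. Each array carried 389307 spots: 371184 spots for 6512 features, each with 19 probes of 60 bases spotted 3 times, and 18123 random-sequence control spots. A table of normalized intensity values, also deposited by the authors, holds 1 value per feature and spot block on a linear scale. RMA (background correction, quantile normalization and median polish) is named in the submitters' processing notes, and its settings are not given in the sources used here. Each deposited column correlated best with the scanner values of its own array (r between 0.992 and 0.993 across features on the log2 scale). The column medians lay between 227 and 249.6, and no gene-wise centring or ratio was present.

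The files name features only by identifiers of the array design, and neither they nor the reference gene table used here pairs these identifiers with locus tags or gene symbols. Gene names, the gacS feature, the gene lists fixed beforehand and the separation of chromosomal from plasmid features were therefore not analysed here. All 6512 features were tested together, which departs from the plan fixed before the data were examined (chromosomal genes only). The rule fixed beforehand took the largest changes with an adjusted p under 0.05, no overlap between the 4 mutant and 4 wild-type arrays, and a higher group mean above background. Only the first 2 rises and the first 2 falls under it are named, because an identifier without a gene name carries little information.

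Spot intensities were background-corrected with normexp (offset 50), quantile-normalized between arrays and put on the log2 scale. The 3 spots of a probe were averaged and the 19 probes of a feature were summarised by median polish. The mutant was compared with the wild type with limma 3.58.1 (lmFit and eBayes, 6 residual degrees of freedom before moderation) in R 4.3.3, with Benjamini-Hochberg adjustment over all 6512 features. Every adjusted p in the text comes from this limma fit unless another setting is named. The background limit of an array was the 95th percentile of its random control spots after normalization. A feature value summarises 57 spots, whereas the limit comes from single spots, so it is a strict limit. Where every array of the dimmer group lay at or below the limit, the fold is given as a lower bound, "at least N-fold". It sets the brighter group's mean over its 4 arrays against the dimmer group's mean of, per array, the higher of the limit and the feature's own value.

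In simulated arrays with background spots drawn from a real array, 6312 unchanged features gave 8 calls, and none of the calls on changed features had the wrong sign. The same array supplied the background of every simulated array, so differences in background between arrays or strains were not simulated. The 8 calls are therefore no error rate for the real counts. Of 50 features simulated with a log2 change of 1, 76.0% were called, but 0 reached a fitted 2-fold change. Of 50 with a log2 change of 2, 90.0% were called and 33 reached it, and of 50 with a change of 3, 38 did. The fitted change was smaller than the simulated change, with a median of 1.24 for a simulated 2 and 1.63 among the 20 brighter of these features, and the cause was not tested. In the simulation the 2-fold count thus missed many features that truly changed by 2-fold or more. The number of arrays limits the precision.

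Neighbouring features were compared along the number in their identifiers. The end of the numbering was divided off at the change point of the share of features above background. Shuffled identifiers or probe orders served as the reference for runs of features and for steps inside features. Extents of the probes were set against the gene lengths of the reference table (assembly MPBAS00001, 6111 genes and pseudogenes) only to test whether the numbering follows gene order. No name and no coordinate was taken from that comparison. Python 3.11.15 was used for these steps. The extraction days recorded in the headers put 7 arrays on 1 day and wild-type replicate 2 alone on another, so the within-day comparison is the comparison without that array. Alternatives fixed beforehand were no background correction, an offset of 0, median scaling, cyclic loess, mean or median of probes, a filter on dim features, the authors' values, a trended robust variance, array weights, the replicate letter as a block, and leaving out each array.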

Results

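The arrays compared colonies of Pseudomonas fluorescens SBW25, a plant-associated soil bacterium, with colonies of a mutant carrying an insertion in gacS. GacS is the sensor kinase of the GacS/GacA two-component system, which in pseudomonads controls secondary metabolites and secreted enzymes through small RNAs and RNA-binding proteins of the Rsm family. The comparison of the strains asks how far loss of this sensor changes the transcriptome. The 8 arrays comprised 4 wild-type and 4 mutant cultures. A feature is the set of 19 probes that the array design gives to a gene, and 6512 features were measured.

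The raw median intensity was 671 ± 118 (SD, n = 4) on the wild-type arrays and 663 ± 111 (SD, n = 4) on the mutant arrays. Random control spots had raw medians of 465 ± 84.0 (SD, n = 4) and 395 ± 153 (SD, n = 4), respectively. After normalization the share of features above the background limit was 53.8% ± 9.70 (SD, n = 4) in the wild type and 64.5% ± 7.74 (SD, n = 4) in the mutant. Relative to the random control spots, the raw median was highest on mutant replicates 1, 2 and 3 and lowest on mutant replicate 4. Whether this contributes to the difference in share was not tested. At most 0.0956% of the spots of an array were at the scanner's ceiling.

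The strains differed far more than the cultures of either strain. Across features, the log2 values of array pairs correlated with r between 0.979 and 0.995 within the wild type, between 0.990 and 0.997 within the mutant, and between 0.774 and 0.791 across strains (features are not independent replicates). The first principal component separated the strains and held 92.3% of the variance. The median SD of a feature between cultures was 0.15 on the log2 scale in the wild type and 0.11 in the mutant.

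A total of 1276 features, or 19.6% of those measured, changed at least 2-fold between the mutant and the wild type. Of these, 612 rose and 664 fell in the mutant. At 2-fold the balance depended on the values used, since the authors' normalized values gave 942 rises and 880 falls. In every other alternative setting falls outnumbered rises at 2-fold, with 721 falls and 535 rises under cyclic loess. Falls outnumbered rises at 4-fold and at 8-fold in the main values and in all 22 alternative settings: 269 features fell and 175 rose at least 4-fold, and 100 fell and 67 rose at least 8-fold. At 16-fold or more, 40 features fell and 33 rose, and at 32-fold or more 17 did each. At 64-fold or more, 8 fell and 3 rose. Over all 6512 features, the 4 mutant and the 4 wild-type values did not overlap in 3597 (55.2%), whereas chance would separate 2.86% of features in this way. Of the 1276 features that changed at least 2-fold, all 19 probes moved in the direction of the feature in 1236 (96.9%), and fewer than 17 did in 9.

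**Figure D1:**
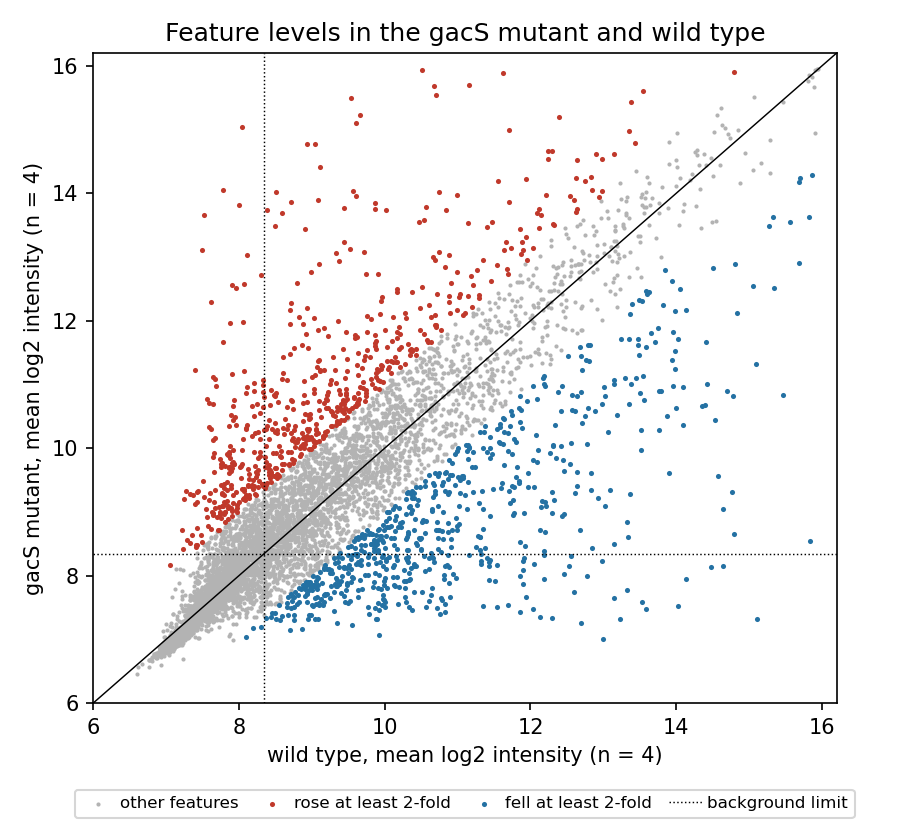
Each point is 1 of the 6512 features, with its mean log2 intensity over the 4 wild-type arrays on the horizontal axis and over the 4 mutant arrays on the vertical axis. The 612 features that rose at least 2-fold lie above the diagonal and the 664 that fell lie below it, and dotted lines mark the mean background limit of 8.34.

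Without a minimum size, 3833 features passed an adjusted p of 0.05 in limma, 2169 upward and 1664 downward. The 2557 features among them that changed less than 2-fold split into 1557 rises and 1000 falls. The excess of rises without a minimum size depended on the normalization. It was smaller under median scaling (1877 rises and 1694 falls) and under cyclic loess (2012 rises and 1777 falls). The random control spots were lower in the mutant by a median log2 difference of -0.15, but not on every array. Their median was 7.37 on mutant replicate 4 and between 7.12 and 7.17 on the other mutant arrays. On wild-type replicate 2 it was 7.24, and on the other wild-type arrays it was between 7.35 and 7.37. Of the 18123 random control spots, 1 passed the same test. They were tested as single spots, whereas a feature value summarises 57 spots, so this is no rate of false calls for features. The median size of the 3833 changes was 0.71 on the log2 scale. The 2-fold count was 1822 from the authors' normalized values and 809 without background correction, and 862 features passed a limma test (treat) of whether the change exceeded 2-fold.

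Some features were above background in 1 strain only. A total of 249 features were above the limit on all 4 mutant arrays and on no wild-type array, and 137 were above it on all 4 wild-type arrays and on no mutant array. The limit differed between arrays, lying between 8.01 and 8.46 in the mutant and between 8.12 and 8.83 in the wild type. Of the former, 138 rose at least 2-fold, and of the latter 134 fell at least 2-fold. Without background correction these numbers were 64 and 81. The median lower bounds of the fold were at least 1.91-fold for the 138 rises and at least 3.16-fold for the 134 falls. Bounds of at least 16-fold were reached by 6 rising and 11 falling features. A further 303 rising and 346 falling features were above background on all 8 arrays. A total of 1493 features were above background on no array, and none of those changed at least 2-fold. Values below the limit on every array leave little room for a 2-fold difference, so this does not show that their RNA was unchanged.

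PFLOURS0000861 rose from 8.05 ± 0.18 to 15.03 ± 0.13 on the log2 scale (SD, n = 4 each). Its limma adjusted p was 1.864e-12, and 1 of its 4 wild-type values was above background, so the size of its rise is uncertain. PFLOURS0000860, the adjoining identifier, rose from 7.79 ± 0.15 to 14.05 ± 0.18 (SD, n = 4 each; limma adjusted p = 3.914e-12). No wild-type array was above background for it, so the rise was at least 47.1-fold in these values, and the order of the 2 rises is not established. PFLOURS0000636 fell from 15.10 ± 0.19 to 7.33 ± 0.16 (SD, n = 4 each; limma adjusted p = 1.864e-12). It was above background on no mutant array, so its level was at least 121-fold lower there in these values. PFLOURS0002376, above background on 3 of the 4 mutant arrays, had a fitted log2 change of -7.29 (SE 0.09, limma adjusted p = 6.687e-13), from 15.84 ± 0.07 to 8.55 ± 0.16 (SD, n = 4 each). In the wild type 29.4% of its spots were at the scanner's ceiling, so its fall is understated and the order of the 2 falls is not established. In each of these 4 features all 19 probes moved the same way. The 8 largest rises and the 8 largest falls by fitted change had a highest limma adjusted p of 1.101e-10. The lower group lay at background on all of its arrays in 4 of these rises and 3 of these falls, for which the size of the change and the rank are uncertain.

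**Figure D2:**
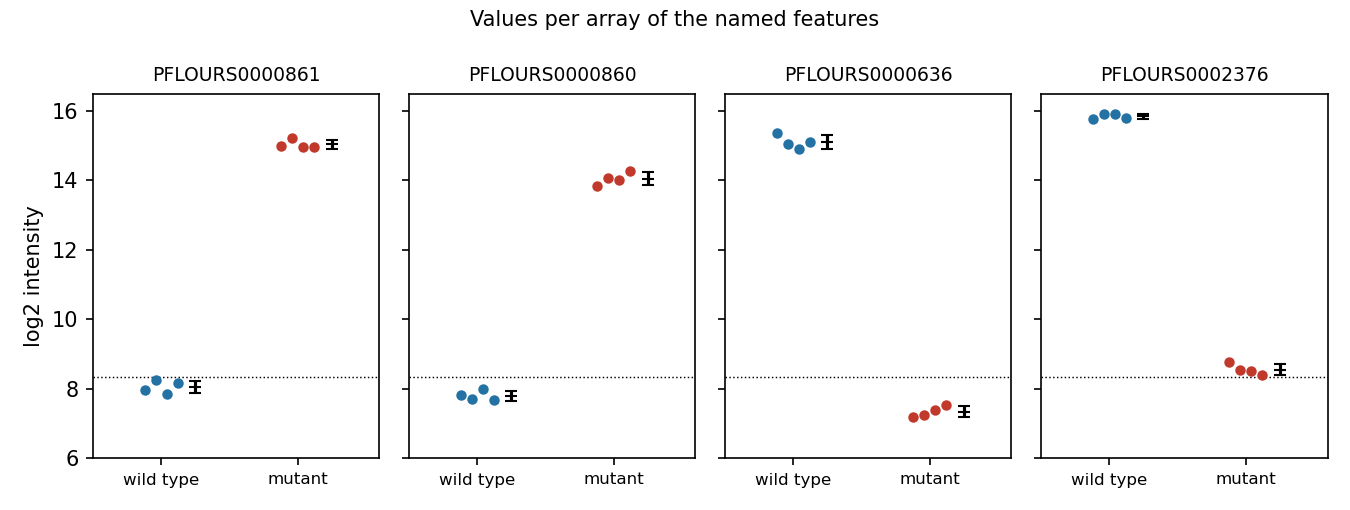
Log2 intensity (vertical axis) of the named features on each of the 4 wild-type (blue) and 4 mutant (red) arrays, with the mean and SD beside the points and the mean background limit of 8.34 as a dotted line. The groups lie far apart in each panel, and the lower group lies at background on all 4 arrays in the middle panels. There the change is at least 47.1-fold (PFLOURS0000860) and at least 121-fold (PFLOURS0000636) in these background-corrected values.

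Features with adjoining identifiers changed together. The log2 changes of adjoining features correlated with r = 0.59 across the 6512 features, whereas the highest value among 1000 shuffles of the identifiers was 0.038 (permutation p = 0.001, the smallest these shuffles can give). The correlation declined to 0.19 at a distance of 5 identifiers and to 0.028 at 20. Of 667 adjoining pairs in which both features changed at least 2-fold, 630 (94.5%) changed in the same direction. Uninterrupted runs of 5 or more features that changed at least 2-fold in the same direction numbered 46, against at most 2 in any of the shuffles, and 26 of these runs fell and 20 rose. They held 358 features, or 28.1% of the 1276. The longest falling run held 19 features with a median log2 change of -1.51, and the next held 16 with a median of -2.07 and included PFLOURS0000636. The longest rising run held 12 features with a median log2 change of 1.61.

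The last 496 identifiers, from number 6017 to 6512, stood apart from the others. Only 5 of these features (1.01%) had a group mean above background, compared with 72.9% of the 6016 features before them. The boundary was placed by the share of features above background, so this contrast describes the stretch and does not test it. Their median log2 change was -0.15, close to that of the random control spots. Mutant replicate 4 did not share this shift, with a median log2 value of 7.24 over the stretch. The other mutant arrays lay between 6.90 and 6.98, and the wild-type arrays between 7.09 and 7.24. In this stretch 37 features passed the test, all of them downward, and 2 of them changed at least 2-fold.

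**Figure D3:**
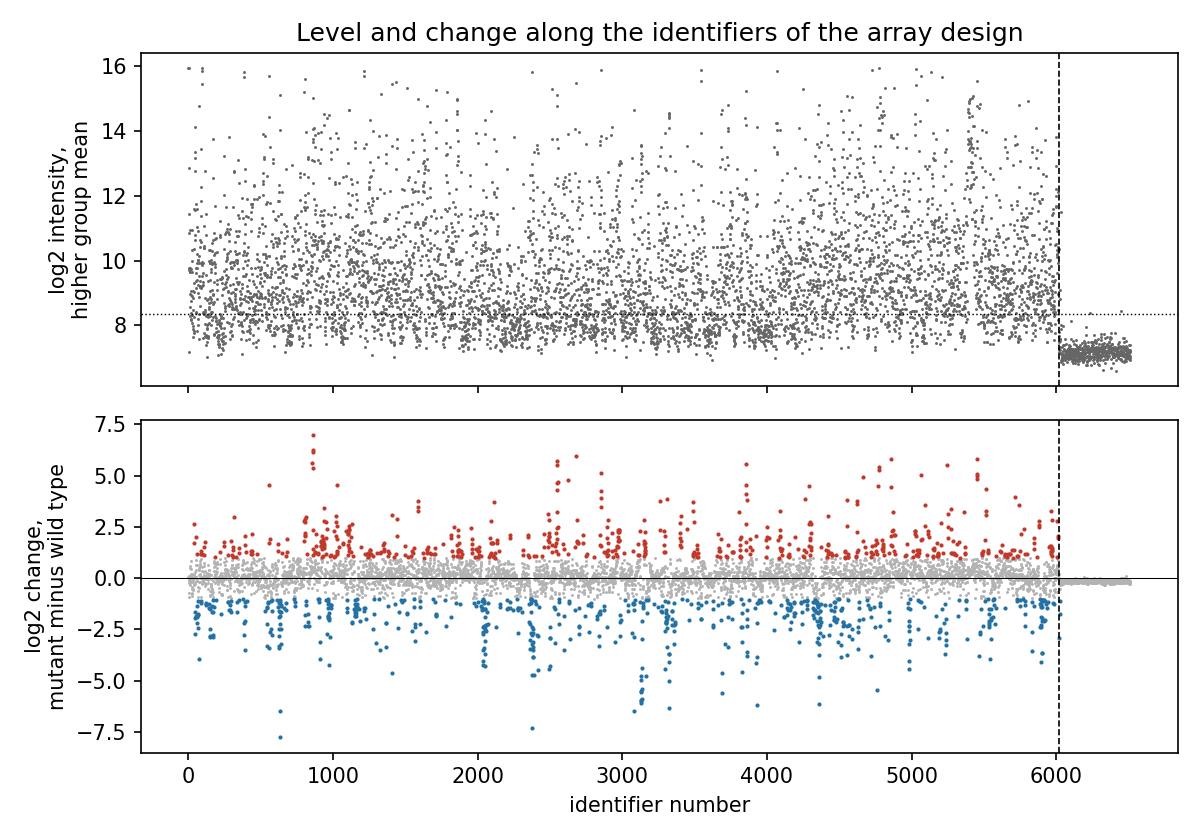
The higher of the 2 group means (upper panel, log2 intensity) and the log2 change of the mutant against the wild type (lower panel) of each feature, in the order of the identifier numbers. Red and blue mark features that rose or fell at least 2-fold, the dotted line is the mean background limit, and the dashed line marks number 6017, after which all but 5 features lie at background.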

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

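In the mutant group, replicate 2 stood apart from the other 3 arrays for PFLOURS0000861, with a log2 value of 15.23 where the others lay between 14.95 and 14.99. The gap exceeded Dixon's 95% limit for 4 values. This was the single outlier among 28 groups of 4 array values examined, and chance gives about 1 in 20. Without that array the feature's fitted log2 change was 6.92, compared with 6.99 over all arrays.

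The counts of changed features were set against other divisions of the same arrays, a comparison made after the counts were known. Of the 35 ways to split the 8 arrays into 4 and 4, only 1, the division by strain, gave 3833 features at an adjusted p of 0.05 in limma or 1276 features at 2-fold or more, and the highest count of any other split was 0 for both. Every other split mixes the strains, so the size of the gap to 0 adds nothing to the share of 1 in 35. That share is the smallest these splits can give. It argues against a chance division of the arrays as the source of these counts but cannot exclude it.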

How the results depend on the processing

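The treat test, the fit without the terminal stretch and the fit without the 2 arrays whose deviations correlated were chosen after seeing the data; the other settings were fixed before the data were examined. Leaving out each array in turn gave between 3483 and 3902 features at an adjusted p of 0.05 and between 1261 and 1302 at 2-fold or more; the comparison within the larger extraction day, without wild-type replicate 2, gave 3678 and 1275. Without background correction the number at 2-fold or more was 809, all of them among the 1276. The numbers above background in 1 strain only were then 64 for the mutant and 81 for the wild type. Background left in adds intensity to both groups and can compress folds, but whether this accounts for the lower numbers was not tested. The authors' normalized values gave 1822 features at 2-fold or more, which included all 1276, and treat gave 862. Under every setting run, the features shared with the main list kept their direction. The lowest and highest counts at an adjusted p of 0.05 in the remaining settings were 3331, without features below background in both groups, and 4566, with array weights. The 4 named features kept their direction and their call in all 22 settings, with a highest adjusted p of 4.96e-09. The sizes of their changes depended on the processing. Without background correction the fitted log2 change was 5.16 for PFLOURS0000860 and -6.46 for PFLOURS0000636. Both are smaller than the lower bounds of 47.1-fold and 121-fold, which hold for the main values only. Replicate letters did not pair the samples: deviations from the group means correlated across features by -0.30, -0.23, 0.05 and 0.19 for the 4 shared letters. With the letter as a replicate block 3683 features passed the threshold and 1276 of them changed at least 2-fold. Settings for gacS, the gene lists and the plasmid features were not run, since the features carry no gene names here. Signal over background limits dim features. The raw median intensity was between 1.33 and 1.52 times that of the random control spots on the wild-type arrays. It was 1.31 times on mutant replicate 4 and between 1.75 and 2.10 times on the other mutant arrays. Whether this difference contributes to the numbers above background or to the balance of rises and falls was not tested.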

Other observations

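The explanations below were tested after the patterns had been seen. Deviations from the group mean correlated between wild-type replicate 1 and mutant replicate 2 with r = 0.69 across features, the highest of the 16 pairs of arrays from different strains. In 113 features the mean of both deviations was at least 0.5 in size on the log2 scale, and in 106 of these it was negative. Without these arrays 1272 features changed at least 2-fold, 1233 of them among the 1276. The mean of both deviations also correlated between adjoining features, with r = 0.40, against at most 0.056 in shuffles. Correlation between adjoining features was thus not particular to the difference between the strains.

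Features with adjoining identifiers changed together. Closeness on the array surface was argued against: the median distance between spots of adjoining features was 0.998 times that of random pairs. A candidate explanation is that the identifiers follow the order of genes on the chromosome, so that runs reflect genes transcribed together. In support, the probe extents of 2716 features (41.7%) fell short of the annotated gene length by at most 60 bases inside gap-free stretches. Such a stretch held at least 10 features in the same order as the genes, not all of which had to fit. In 10 shuffled orders 0 features fitted in this way. Whether runs correspond to single transcripts was not tested, and probes shared between similar neighbours remain open.

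Of the last 496 identifiers, all but 5 lay at background in both strains. A dim part of the array is argued against, since the fullest quadrant of the array held 25.1% of their spots. The design text names plasmid sequences beside the chromosome, and a hypothesis is that these features may represent sequences outside the chromosome that both strains lack. None of them, 0%, fitted an annotated chromosomal gene length inside a gap-free stretch, compared with 45.1% of the features before them. All features were aligned once, in order, so the 6016 earlier features could use up most of the 6111 annotated genes. Few genes were then left for the last identifiers whatever their origin, so the 0% does not bear on the hypothesis. Probes that hybridise poorly cannot be told apart from missing sequences, because only 1.01% of these features exceeded background and no array came from a strain known to carry them.

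Some features split into parts that changed differently. A step of at least 2 on the log2 scale between probes on either side of a position, with at least 4 probes on each side and a t statistic across probes of at least 10, was found in 11 features, and in none of 100 shuffles of the probe order. In 3 of them the parts changed in opposite directions. In the sharpest of the 11, the first 15 probes had a log2 change of -0.34 ± 0.16 (SD over probes) and the 4 probes from position 2266 onward had -2.95 ± 0.04, in a feature whose probes reached position 2419. The less changed side lay at background in both strains in 0 of the 11, which argues against missing signal in both strains there. Background in 1 strain alone, which would limit the change on that side, was not tested. Among all features that changed at least 2-fold, 69.4% had an adjoining feature that changed at least 2-fold in the same direction. In all 11, including the 8 whose parts changed in the same direction, an adjoining feature changed at least 2-fold like the more changed side. Parts of features could be carried on the transcript of a neighbour, but this comparison cannot decide it. It accepted a neighbour at either end, without checking that it adjoined the more changed part. The more changed side is also arbitrary where opposed parts changed by similar amounts (-2.20 and 2.21, and -1.16 and 0.98). The insertion in gacS could produce a step of this kind, but with 11 such features and no gene names it stays open whether any of them is gacS.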
